A study of Mus musculus with 20 samples.

How the data were processed

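The series holds 20 PAS-seq libraries from mouse cells. PAS-seq sequences the 3' ends of polyadenylated RNA: cDNA is primed with oligo(dT), circularised and amplified, so that a read marks the poly(A) site a transcript used. The fibroblasts were embryonic and carried a doxycycline-inducible cassette for the reprogramming factors Oct4, Klf4, Sox2 and c-Myc (OKSM) in the 3' untranslated region of Col1a1. They were transfected with siRNA against Nudt21 or with luciferase siRNA, or left untransfected, and OKSM was induced for 3 or 6 days. Uninduced fibroblasts (MEFs) and induced pluripotent stem cells (iPSCs) mark the start and the end of reprogramming.

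The deposited table gives raw read counts per poly(A) site, with each site's gene symbol, gene identifier, type of place (last exon, intron or upstream exon), strand and coordinate. The submitters' processing notes name TopHat2 2.1.0, deepTools 2.4 and genome build mm9 without saying what each did. How sites were called, whether reads primed inside A-rich sequence were removed and whether coordinates count from 0 or 1 are not stated. The table held 96332 sites of 16059 genes in 20 count columns. Of these sites 59574 lay in last exons, 33185 in introns and 3573 in upstream exons. The reference annotation of assembly GRCm38.p6 served for names only. It matched 15893 gene identifiers (99.0%), and 1710 of them now carry another symbol. Symbols are printed as the table gives them, with the current one in brackets at first mention where it differs for a gene named by the rule below.

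18 columns were matched to samples by name. The remaining 2 columns carry only a day as their name, so they were not used, and the comparison of SSEA-positive with SSEA-negative cells, planned with 2 alternatives of its own, was not made. SSEA is a surface antigen gained during reprogramming. The 2 SSEA-positive libraries, 1 at each of days 6 and 9, belong to no replicated group and enter no test. The other 16 libraries form 8 groups of 2. The labels do not say whether replicates came from separate cultures, so the p-values measure the spread between these samples.

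The table gives the same coordinate more than once in 1800 entries. Such an entry was kept only where it was the sole last exon entry at its coordinate. The others were removed, 1695 sites with 4.02% of the counts, leaving 94637 sites of 15871 genes. Library totals ran from 754609 to 13032080 counts. 10 libraries held 6939231 to 13032080 (with 0.228 to 0.263% of counts in upstream exons) and 6 held 754609 to 4069176 (0.293 to 0.310%). The labels give no sequencing batch. Both Nudt21 siRNA and control libraries of day 3 lay in the deeper set. At day 6 the Nudt21 siRNA libraries lay in the deeper set and their controls in the shallower. The comparisons of untransfected day 3 cells and of iPSCs with MEFs also crossed the sets, and the comparison of untransfected day 6 cells with MEFs did not. Folds against a group with no counts are given as lower bounds, from 3 counts over the group's 2 libraries. Ratios with 1 to 3 counts in a group carry a 95% counting interval (exact binomial). Intervals and limits cover counting error only, since no molecular identifiers were used.

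Expression was tested with edgeR 4.0.16 (quasi-likelihood F-test) in R 4.3.3 on counts summed over the sites of a gene. Normalisation was by TMM and genes were kept by filterByExpr (minimum count 10). One fit over the 16 libraries with a term per group gave 8 comparisons, and Benjamini-Hochberg adjusted p under 0.05 was called. Polyadenylation was tested with edgeR's diffSpliceDGE on the 2 most used sites of each gene, among sites with at least 10 counts in at least 2 libraries and at least 5% of the gene's reads. The value is the change in log2(distal/proximal). It is negative when use moves to the proximal site, the upstream one on the gene's strand. The 5706 pairs had a median gap of 859.5 bases. Both sites lay in the last exon in 5013 pairs (87.9%), and 590 pairs (10.3%) joined an intronic with a last exon site. CPM are counts-per-million of the counts used. Values are given as mean and SD with n = 2, and log2 changes with their standard error (SE).

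Gene lists, 20 in number, were tested in the 8 comparisons with camera at a preset correlation of 0.01, adjusted over all lists and comparisons, and again with the correlation estimated per list. The lists are cleavage and polyadenylation factors, trithorax and COMPASS, PAF1 complex, Polycomb, BAF and chromatin assembly, pluripotency, epithelial, mesenchymal and fibroblast, proliferation, interferon response, p53 and senescence, immune cells, keratinocyte, extraembryonic and endoderm, neural, muscle and endothelial, translation, oxidative phosphorylation, glycolysis, and published Nudt21 polyadenylation targets. Lists, comparisons, tests and the rule for named genes were fixed before the data were examined. The rule names Nudt21, the list members of smallest adjusted p (here 2 for each list in the comparisons of Nudt21 with luciferase siRNA), and per comparison the 5 highest and 5 lowest log2 fold changes among called genes of at least 10 CPM in the higher group whose libraries do not overlap. For sites it names the 6 largest called shifts to proximal and the 4 largest to distal, with both sites at 5 CPM or more in a group and no overlap of distal share. Wdr5, Rybp, Cpsf6, Cstf2, Hcfc1 and Rbbp5, members of the lists, were chosen as site examples after their values were seen. Klf4, Sox2 and c-Myc counts can include the transgene. Pou5f1, Zfp42 and Sall4 are not in the table and are not analysed here.

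Alternatives were DESeq2 1.42.0 size factors, the DESeq2 Wald test, no filter on low counts, the groups compared alone, replicate number as a block, each replicate left out, a minimum fold of 1.5, all sites with a Simes p, site minimums of 10% or 30 counts, limma 3.58.1 voom with diffSplice, a minimum change of 15 percentage points, last exon sites alone, sites at least 200 bases apart and genes of at least 10 CPM. Alternatives chosen after seeing the data were thinning every library to 725701 counts, keeping shared sites, untransfected libraries or day 3 luciferase siRNA libraries as control, leaving out genes changed by the luciferase siRNA, and untransfected day 6 cells in place of iPSCs. Tests across groups of 2 do not allow tests for single outlying samples or other splits of the samples.

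The tests were run on counts simulated from the fitted group means and from the trend of spread with expression level. At day 3 they recovered 62.7, 79.1 and 92.2% of genes changed 1.5, 2 and 4-fold, with 10 of 12123 unchanged genes called, and at day 6 28.4, 72.3 and 76.6%, with 4 of 12144 called. Site shifts of 0.5, 1 and 2 log2 units were recovered in 13.4, 47.8 and 86.4% of pairs at day 3 and in 1.49, 13.4 and 33.3% at day 6. A list of 15 genes raised 2-fold was called, and 0 of 20 random lists were. Genes were drawn independently of each other, so these list results do not cover correlation between the genes of a list. The simulation left out variation in spread between genes around that trend, and it changed only 200 genes or pairs. Far more were called at day 3 in the real data, so these rates need not hold there.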

Results

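Poly(A) site use and transcript levels were measured by PAS-seq in mouse embryonic fibroblasts reprogrammed with OKSM. Replicated groups of 2 libraries each were uninduced MEFs, iPSCs, and cells induced for 3 or 6 days that were untransfected, transfected with luciferase siRNA, which has no target in mouse cells, or transfected with siRNA against Nudt21. Nudt21 encodes the smaller subunit of cleavage factor I, which binds upstream of poly(A) sites. Total counts at day 3 were 7541366 and 11300295 for Nudt21 siRNA, 13032080 and 11904811 for luciferase siRNA and 9052850 and 12889534 for untransfected cells. At day 6 they were 8966491 and 10025881 for the libraries labelled Nudt21 siRNA, 781784 and 754609 for luciferase siRNA and 1556626 and 1563519 for untransfected cells. MEF libraries held 2976291 and 4069176, iPSC libraries 6939231 and 7344125, and the single SSEA-positive libraries 6019370 at day 6 and 11881075 at day 9. Of 12449 genes tested for expression, 5706 had a pair of poly(A) sites that could be tested.

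Nudt21 mRNA fell with its siRNA at day 3, from 74.4 ± 0.642 CPM (SD, n = 2) with luciferase siRNA to 25.4 ± 3.89 CPM. The log2 fold change was -1.53 (SE 0.11, 95% interval -1.75 to -1.31, adjusted p = 5.96e-26). At day 6 it was not lower: 36.2 ± 0.463 CPM in the libraries labelled Nudt21 siRNA and 29.0 ± 5.95 CPM with luciferase siRNA, where the libraries held 25 and 18 counts. That log2 change was 0.19 (SE 0.24, 95% interval -0.28 to 0.66, adjusted p = 0.611). The day 6 libraries are therefore called the libraries labelled Nudt21 siRNA at 6 days, and directions drawn from them rest on that label. Nudt21 was also higher in untransfected day 3 cells (76.0 ± 0.660 CPM) than in MEFs (10.6 ± 3.09 CPM), by 2.53 log2 units (SE 0.16, adjusted p = 1.12e-30), and in iPSCs (60.3 ± 3.17 CPM), by 2.33 (SE 0.17, adjusted p = 1.14e-26). In untransfected day 6 cells, at 15.0 ± 5.16 CPM, the change of 0.23 from MEFs (SE 0.29, adjusted p = 0.567) did not pass. Both rises set deeper against shallower libraries, and each group of shallower libraries read low in Nudt21 (MEFs, untransfected and luciferase siRNA cells of day 6). Luciferase siRNA minus untransfected cells stood at -0.04 for Nudt21 at day 3 (adjusted p = 0.818) and at 0.93 at day 6 (SE 0.32, adjusted p = 0.092), and neither passed.

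**Figure D1:**
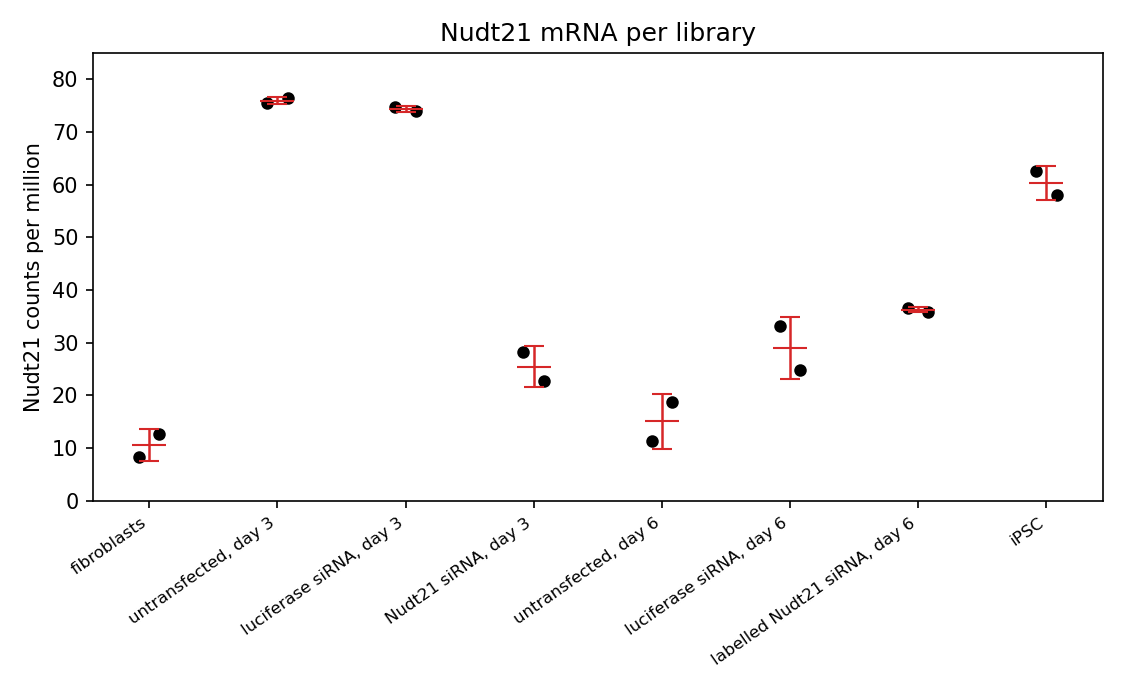
Nudt21 counts-per-million (vertical axis) in each library of the 8 groups, 1 point per library, with red lines for the mean and SD. Nudt21 siRNA libraries of day 3 lay at 28.2 and 22.7, below luciferase siRNA (mean 74.4), and the libraries labelled Nudt21 siRNA at 6 days (mean 36.2) were not below theirs (mean 29.0).

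The comparison of Nudt21 with luciferase siRNA at day 3 asks what loss of Nudt21 does early in reprogramming. Poly(A) site use moved to the proximal site in 3492 genes and to the distal site in 295, out of 5706, so that 92.2% of the 3787 called shifts were proximal. The median change in log2(distal/proximal) over all pairs was -1.29. Across 2334 genes the distal site took on average 45.0 and 44.8% of the pair's reads in the Nudt21 siRNA libraries against 61.8 and 61.6% with luciferase siRNA and 61.9 and 62.0% in untransfected cells. At least 15 percentage points were gained by the proximal site in 2511 genes and by the distal site in 139. Pairs within the last exon went to proximal in 3211 of 3397 calls (94.5%) and pairs of an intronic and a last exon site in 236 of 337 (70.0%). The share of counts in introns was 1.54 and 1.55% with Nudt21 siRNA against 1.13 and 1.18% with luciferase siRNA.

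Genes were ranked by the fitted log2(distal/proximal), which has no exact value where a site had 0 reads. The order differs from that of the percent shares. Jmjd1c, a histone demethylase gene, came first among shifts to proximal at day 3. Its distal site (mm9 chromosome 10, plus strand, 66719068, against 66718362 for the proximal one) took 46.5 ± 3.46% of the pair's reads (SD, n = 2) with Nudt21 siRNA and 100% with luciferase siRNA, where 0 of 1033 reads were proximal, which allows a share of up to 0.290%. For Pum1, a translational repressor (chromosome 4, plus strand, 130336013 and 130337479), the distal share was 62.5 against 100%, with a proximal share of up to 0.206% allowed in the control. For Cdyl, a chromodomain protein (chromosome 13, plus strand, 35964685 and 35965901), it was 75.8 against 100%, with up to 0.312% allowed. Zswim6 had 49.9 against 99.8%, the kinase gene Prkx 31.7 against 99.4% and Rapgef2 55.9 against 99.8%. The first 4 shifts to distal were in Papolg, a poly(A) polymerase, with 57.7 ± 8.14 against 0.877%, Papd5 (now Tent4b), another poly(A) polymerase, with 74.3 against 4.70%, Gls and Araf. In Gls, glutaminase, the last exon site (chromosome 1, minus strand, 52220293) took 85.7 ± 1.49% against 17.9 ± 0.980%, the rest being at an intronic site (52242124). In the kinase gene Araf the last exon site took 91.3 against 38.6%.

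Among chromatin regulators and the 3' end processing machinery most called shifts at day 3 were proximal, as over all pairs (3492 to proximal and 295 to distal of 5706), and no list was tested for more shifts than other genes. Of 9 trithorax and COMPASS genes with a pair (histone H3 lysine 4 methylation), 7 shifted to proximal and 0 to distal, of 15 Polycomb genes 13 and 0, of 3 PAF1 complex genes 2 and 0, of 4 BAF and chromatin assembly genes 2 and 1, and of 13 cleavage and polyadenylation factors 8 and 3. Numbers adjusted over the list alone were the same, 7, 13, 2, 3 and 11 called. In Wdr5, a core subunit of these methyltransferases, the share of the distal site (chromosome 2, plus strand, 27392055) fell from 93.5 ± 0.550% to 42.7 ± 5.79%, a shift of -4.28 (SE 0.19). Its proximal site stood at 75.8 ± 5.23 CPM with Nudt21 siRNA against 5.04 ± 0.264 CPM, and its distal site at 56.6 ± 9.46 against 72.5 ± 2.76 CPM. The Polycomb gene Rybp went from 90.6 ± 0.239% to 19.0 ± 2.38% distal (chromosome 6, minus strand, 100178552 distal and 100181884 proximal), Cpsf6, the partner subunit of Nudt21, from 62.3 to 4.71%, Cstf2 from 76.4 to 19.5%, Hcfc1 from 96.2 to 63.5% and Rbbp5 from 82.5 to 46.9%. Of 11 published Nudt21 targets with a pair 10 shifted to proximal and 0 to distal. That list includes Wdr5 and Rybp, which the study itself reported, so its count is not independent evidence. edgeR called these shifts at adjusted p under 0.05. Internal priming cannot be judged from the table.

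**Figure D2:**
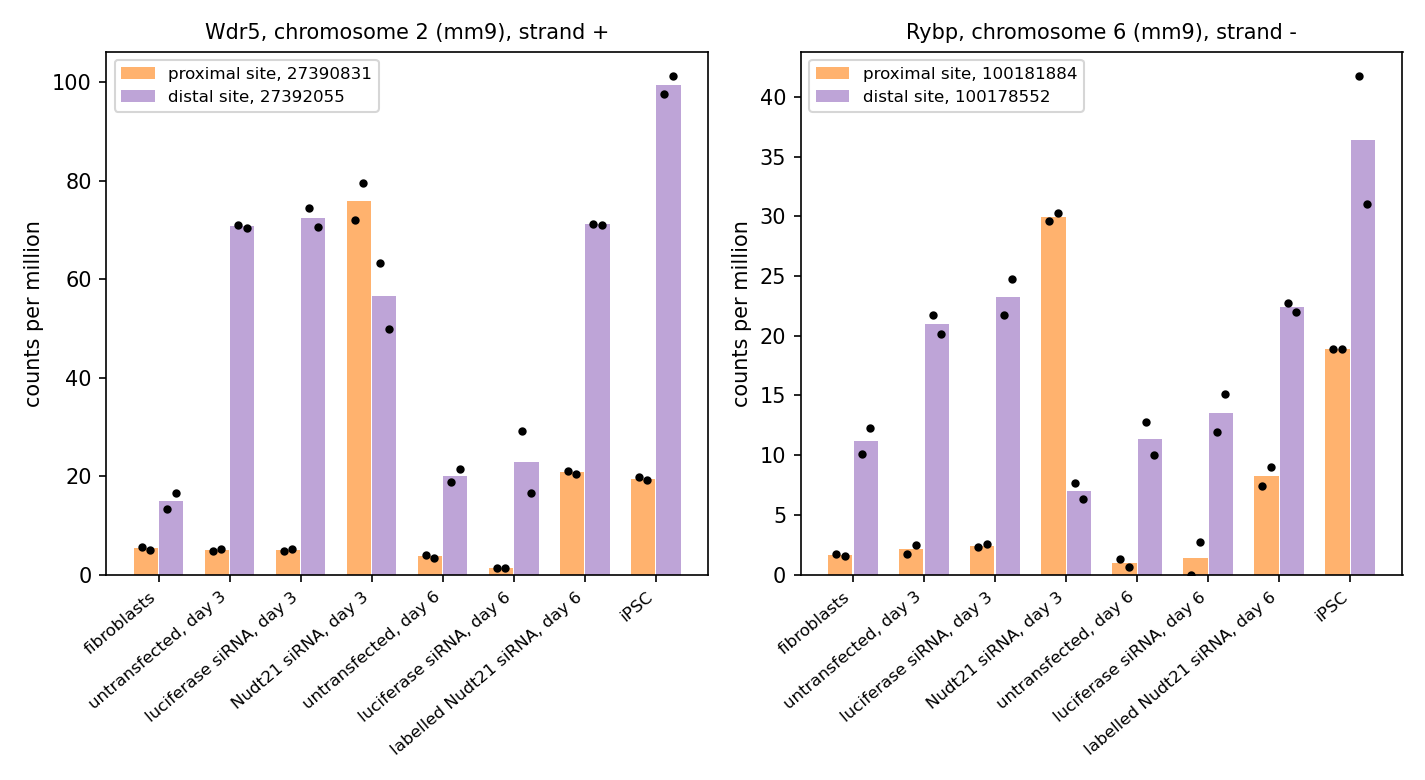
Counts-per-million (vertical axes) at the proximal and distal site of Wdr5 and Rybp in the 8 groups, bars for the mean of 2 libraries and points for each library. At day 3 the proximal Wdr5 site stood at 75.8 with Nudt21 siRNA and 5.04 with luciferase siRNA, and the distal site at 56.6 and 72.5.

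**Figure D3:**
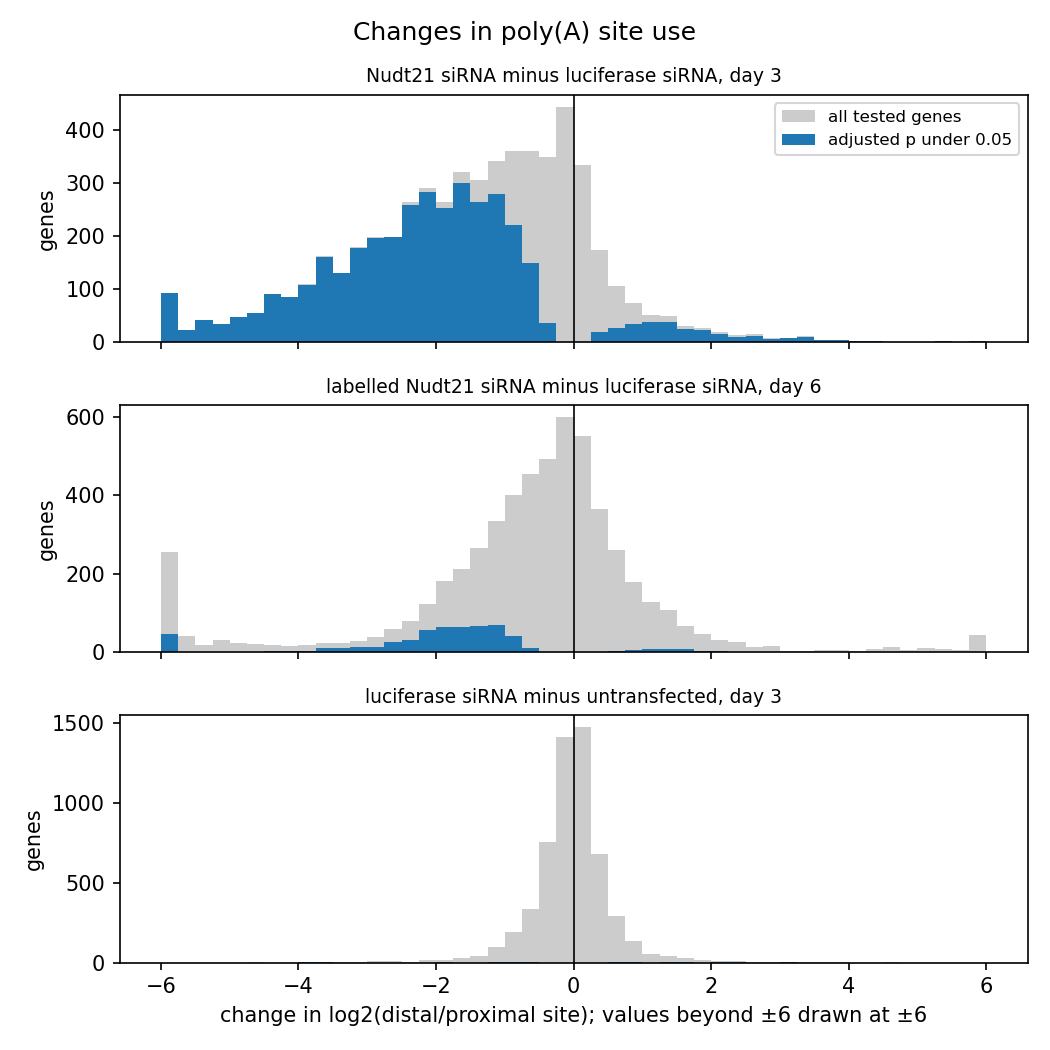
Number of genes (vertical axes) by change in log2(distal/proximal) for 3 comparisons, all 5706 tested pairs in grey and called ones in blue. With Nudt21 siRNA at day 3 the median was -1.29, and with luciferase siRNA against untransfected cells at day 3 it was -0.01.

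In expression, 3402 genes were higher and 2919 lower with Nudt21 siRNA than with luciferase siRNA at day 3. Mesenchymal and fibroblast genes fell: 28 of 29 were lower and 1, Lum, was higher by 2.55 (SE 0.58) at 2.00 CPM (the same adjusted over the list alone), with a median of -1.14 (camera adjusted p = 1.44e-21, adjusted p = 0.0076 with an estimated correlation). Lox, which cross-links collagen, changed by -2.20 (SE 0.08, adjusted p = 3.62e-53) and the actin-binding Tagln by -1.85. Interferon response genes were lower in 18 of 18 cases (18 adjusted over the list alone), with a median of -5.19 (adjusted p = 4.05e-25, and adjusted p = 0.0132 with an estimated correlation). Isg15, a ubiquitin-like protein, stood at 1.24 against 310 CPM (-7.82, SE 0.16) and Oasl2 at 0.849 against 183 CPM (-7.47, SE 0.19). Against untransfected cells, a control added after the data were seen, the interferon list was not called (2 rose and 1 fell of 18, adjusted p = 0.905, Isg15 0.12, Oasl2 0.40), while 25 of 29 mesenchymal genes were again lower (adjusted p = 7.32e-15, and adjusted p = 0.00604 with an estimated correlation).

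No other list was called at day 3 between Nudt21 and luciferase siRNA. Cleavage and polyadenylation factors rose in 9 and fell in 1 of 20 (adjusted p = 0.195). Cpsf6 rose by 1.51 (SE 0.08). Trithorax and COMPASS genes rose in 4 and fell in 2 of 14 (adjusted p = 0.287), among them Wdr5, higher by 0.98 (SE 0.09), and Dpy30, higher by 0.81. Polycomb genes rose in 10 and fell in 3 of 22 (adjusted p = 0.287), with the methyltransferase Ezh2 at 0.97 and Rnf2 at 0.88. The PAF1 complex had 2 higher and 1 lower of 6 (Cdc73 0.97, Rtf1 0.28, adjusted p = 0.757), and BAF and chromatin assembly 5 and 4 of 15 (Smarce1 -1.34, Hdac2 0.57, adjusted p = 0.935). Pluripotency genes rose in 4 and fell in 3 of 13 (adjusted p = 0.756). The threonine dehydrogenase gene Tdh stood at 1.70 (SE 0.17) and Klf4 at -1.41, whose counts can include the transgene. Against untransfected cells Tdh was not called, at 0.04 (adjusted p = 0.833), and luciferase siRNA itself lowered it by 1.66 log2 units. Epithelial genes rose in 4 of 12 (adjusted p = 0.228). Fut9, which makes the SSEA epitope, stood at 3.50 (SE 0.29) and Dsp at 1.86. Proliferation genes rose in 10 and fell in 2 of 20 (adjusted p = 0.181; Ccnb1 -1.56, Ccna2 0.55), and p53 and senescence genes rose in 8 and fell in 2 of 13 (adjusted p = 0.161, Serpine1 -1.73, Trp53inp1 0.76). Serpine1, Trp53inp1 and Fhl1 changed sign against untransfected cells, at 0.47, -0.11 and 0.07.

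No list of markers of other cell types was called at day 3. Perp, an epidermal adhesion gene, rose by 2.48 (SE 0.08) and Sfn fell by 1.03 on the log2 scale, while 4 other keratinocyte genes were not called (adjusted p = 0.765). Sfn was higher, by 1.46, against untransfected cells. Neural genes rose in 3 and fell in 4 of 9 (Nefl 3.79, Nes -1.07, adjusted p = 0.992), extraembryonic genes in 1 and 1 of 7 (Dab2 -1.57, Lama1 1.16, adjusted p = 0.992), immune genes in 1 and 0 of 4 (Cd53 1.76 at 1.38 CPM, Lyz2 not called, adjusted p = 0.992) and muscle and endothelial genes in 0 and 1 of 7 (Des -1.11 at 1.26 CPM, Tnnt2 not called, adjusted p = 0.647). Translation genes rose in 11 and fell in 2 of 15 (Eef1a1 1.5, Rps6 -2.26, adjusted p = 0.0675), oxidative phosphorylation genes in 9 and 0 of 15 (Atp5a1 0.65, Sdhb 0.53, adjusted p = 0.0679), glycolysis genes in 6 and 2 of 14 (Pdk1 1.48, Pfkp 0.76, adjusted p = 0.328) and published targets in 5 and 5 of 15 (Timp2 -1.27, Fhl1 -1.03, adjusted p = 0.996). For the keratinocyte, extraembryonic, neural and published target lists, median, mean and test differed in sign. Adjusted over the list alone, p53 and senescence genes rose in 9 and PAF1 genes fell in 2, and the other counts of this comparison were the same. Without Nudt21 siRNA replicate 2 Rtf1, Cd53 and Des were not called (adjusted p = 0.19, 0.201 and 0.0665), nor were Rtf1 and Cd53 without luciferase siRNA replicate 2 (0.0565 and 0.0747) or Rtf1 without luciferase siRNA replicate 1 (0.0971). The 5 largest rises were Prrg4 (5.51, SE 0.16, 102 against 2.31 CPM), AI848285 (now Shisa8, 4.98), Mob1a, a Hippo pathway protein (4.91), Mybl1 (4.68) and Poc1b (4.65). The 5 largest falls were all interferon-induced genes: Ifi44 (-8.38, SE 0.24), Usp18 (-8.24), Ifit1 (2 against 964 counts, a ratio of 364 with an interval of 100 to 3008), Isg15 and Oasl2. Against untransfected cells none of these 5 was called. There Ifi44 stood at -0.61 (adjusted p = 0.502) and Usp18 at -0.84 (adjusted p = 0.312). Isg15 stood at 0.12 and Oasl2 at 0.40, and Ifit1 had an adjusted p of 0.476. The count of called genes was 3451 with a fold of at least 1.5 and 2247 with libraries thinned to 725701 counts.

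Genes whose pair shifted to proximal by at least 15 points at day 3 were higher in expression in 1011 of 2511 cases (40.3%) and lower in 523 (20.8%), with a median of 0.15. Of 139 genes shifted as far to distal, 63 were higher (45.3%) and 21 lower (15.1%), with a median of 0.28. Of the 1890 genes with no called shift 487 were higher (25.8%) and 502 lower (26.6%).

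The same comparison at day 6 asks what the siRNA does as cells approach pluripotency, and its directions rest on the label of libraries in which Nudt21 mRNA was not lower. In the libraries labelled Nudt21 siRNA at 6 days, 558 genes shifted to proximal and 54 to distal against luciferase siRNA (91.2% proximal, median change -0.41, or -0.28 with pairs holding a site at 0 counts at their bounds). Mean distal shares were 58.3 and 58.2% against 62.9 and 62.6%. Fgfr1op (now Cep43), a centrosomal gene, had a distal share of 55.3 ± 0.0420% against 100% (0 of 32 proximal reads, up to 9.38% allowed). Dync1i2, a dynein subunit, had 93.1 against 100% (up to 0.980% allowed), the cholesterol transporter gene Abca1 92.9 against 100% (up to 1.44%), Fndc3b 91.5 (up to 1.88%), the exonuclease gene Xrn1 72.8 (up to 7.89%) and Enox2 57.7 (up to 15.8%). Shifts to distal named by that ranking were in 2610528E23Rik (now Cmss1, 75.5 against 18.6%), Papd5 (32.6 against 3.13%), Ccdc43 (84.2 against 40%) and the kinase gene Cdk8 (37.6 against 7.04%). Of 11 published targets 2 shifted to proximal (3 adjusted over the list alone), and of 9 trithorax and 15 Polycomb genes 0 were called. Of the 558 proximal genes, 519 (93.0%) were also called proximal at day 3, against 341 expected for independent calls. That expectation gives every pair the same probability of a call whatever its read count, so an excess need not mean a shared effect. Against luciferase siRNA libraries of day 3 Ccdc43 shifted the other way, by -0.51. With that control 25 of the 54 distal genes kept their sign and 10 were called proximal. Of the 558 proximal genes 474 kept it and 21 were called distal. Calls fell to 275 without luciferase siRNA replicate 1 and to 296 without replicate 2, and 370 changed by 15 points or more. Enox2, Papd5 and Ccdc43 were not called without luciferase siRNA replicate 1 (adjusted p = 0.101, 0.0909 and 0.0616), nor was Papd5 without replicate 2 (0.202).

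In expression at day 6, pluripotency and epithelial genes were higher and fibroblast genes lower in the libraries labelled Nudt21 siRNA, again a direction that rests on that label. Pluripotency genes rose in 8 and fell in 1 of 13 (10 and 1 adjusted over the list alone), with a median of 3.14, or 2.22 with 3 genes at their lower bound (adjusted p = 6.04e-07, and adjusted p = 0.0147 with an estimated correlation). Utf1, a chromatin factor of embryonic stem cells, reached 81.2 CPM against 0 counts, at least 39.9-fold higher, and Tdh rose by 3.14 (SE 0.18, adjusted p = 8.52e-34). Epithelial genes rose in 7 of 12 (10 adjusted over the list alone), with a median of 3.23, or 2.4 with 3 at their bound (adjusted p = 3.63e-06, and adjusted p = 0.0306 with an estimated correlation). E-cadherin, Cdh1, stood at 108 against 1.33 CPM, a ratio of 79.9 with an interval of 22.1 to 660, and Krt8 rose by 3.64 (SE 0.27). Mesenchymal and fibroblast genes fell in 24 and rose in 0 of 29 (27 fell adjusted over the list alone), with a median of -0.86 (adjusted p = 3.54e-27, and adjusted p = 0.00452 with an estimated correlation), Tagln by 2.22 and Col1a2 by 1.5 on the log2 scale. Proliferation genes rose in 15 of 20 (17 adjusted over the list alone), with a median of 0.63 (adjusted p = 8.29e-08, and adjusted p = 0.0211 with an estimated correlation), led by Cdc20 (1.55, SE 0.17) and Top2a (1.44).

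Another 8 lists were called at day 6 with the preset correlation alone. Trithorax and COMPASS genes rose in 8 of 14 (adjusted p = 0.00558, and adjusted p = 0.235 with an estimated correlation), with Wdr5 at 1.86 (SE 0.21) and Dpy30 at 0.94. Against luciferase siRNA libraries of day 3 this list rose in 3 and fell in 4, and Dpy30 changed sign. The proximal and distal Wdr5 sites stood at 5.04 and 72.5 CPM in those libraries, and at 20.8 and 71.1 CPM in the libraries labelled Nudt21 siRNA at 6 days. Polycomb genes rose in 12 and fell in 1 of 22 (adjusted p = 0.00523, and adjusted p = 0.0592 with an estimated correlation), with Suz12 at 1.39 and Jarid2 at 1.78. Cleavage and polyadenylation factors rose in 7 of 20 (adjusted p = 0.00845, and adjusted p = 0.165 with an estimated correlation), with Cpsf3 at 0.98 and Cpsf1 at 1.00. These factors rose in 2 and fell in 9 against luciferase siRNA libraries of day 3, where Cpsf3 changed sign. Interferon genes rose in 6 of 18 (9 adjusted over the list alone; adjusted p = 0.0323, and adjusted p = 0.331 with an estimated correlation), with the RNA sensor Ddx58 at 1.30 and Bst2 at 0.90. Genes of the p53 list rose in 5 and fell in 3 of 13 (6 and 3 adjusted over the list alone; adjusted p = 0.0265, and adjusted p = 0.113 with an estimated correlation), with Trp53inp1 at 1.22 and Mdm2, which restrains p53, at 1.16. Keratinocyte genes rose in 2 of 6 (adjusted p = 0.00218, and adjusted p = 0.0591 with an estimated correlation), Perp by 2.12 and Sfn by 2.73. Translation genes fell in 10 and rose in 1 of 15 (adjusted p = 9.37e-06, and adjusted p = 0.22 with an estimated correlation), with Eef2 at -1.03 and Rps8 at -0.84, and glycolysis genes fell in 7 and rose in 3 of 14 (adjusted p = 0.0106, and adjusted p = 0.179 with an estimated correlation), with Ldha at -0.92 and Pkm2 at -0.76. The glycolysis mean was positive at 0.30, against a median of -0.27. The interferon call ended without the second library labelled Nudt21 siRNA (adjusted p = 0.0540) or luciferase siRNA replicate 2 (adjusted p = 0.102), and the p53 call without luciferase siRNA replicate 1 (adjusted p = 0.0508).

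The remaining 8 lists were not called at day 6. The PAF1 complex rose in 2 of 6 (Wdr61 0.82, Leo1 0.76, adjusted p = 0.243), BAF and chromatin assembly in 5 with 1 lower of 15 (Hdac2 1.16, Hdac1 0.70, adjusted p = 0.287), extraembryonic genes in 2 with 1 lower of 7 (Dab2 -1.17, Tfap2c at least 6.72-fold higher, adjusted p = 0.792), neural genes in 1 with 3 lower of 9 (Stmn2 -1.22, Nefl 2.36, adjusted p = 0.647), muscle and endothelial genes in 1 with 1 lower of 7 (Tek -0.71, adjusted p = 0.979), oxidative phosphorylation in 1 with 5 lower of 15 (Cox4i1 -0.46, Ndufa4 0.31, adjusted p = 0.177), published targets in 5 with 4 lower of 15 (Fhl1 -1.34, Timp2 -1.02, adjusted p = 0.718) and immune genes in 0 of 4 (adjusted p = 0.992). Adjusted over the list alone, 1 more gene was lower in the BAF, neural and oxidative phosphorylation lists. There was 1 more higher in the extraembryonic list. In the immune, neural, muscle and published target lists median, mean and test differed in sign. In all 1833 genes were higher and 1668 lower. The 5 largest rises, all against 0 counts with luciferase siRNA, were Utf1, Mmrn2 (at least 21.1-fold), the tight junction gene Cldn6 (16.9), Ly6g6c (12.5) and Zbtb32 (12.2). The 5 largest falls were Mapk11 (-2.66, SE 0.57), Tmc3 (-2.54), Fmo1 (-2.43), Slc13a5 (-2.4) and Fibin (-2.37). Mapk11 stood at 10.9 ± 9.85 CPM with luciferase siRNA (16 counts). Without luciferase siRNA replicate 2 Mapk11 was at -1.19 (adjusted p = 0.511) and Fibin at -1.72 (adjusted p = 0.148), and neither was called. Against the luciferase siRNA libraries of day 3 Fmo1 stood at 0.11 (adjusted p = 0.814), and against untransfected day 6 cells Slc13a5 stood at -0.65 (adjusted p = 0.326). With the luciferase siRNA libraries of day 3 as control BAF and chromatin assembly genes rose in 1 and fell in 8 of 15, and Hdac1 changed sign. Leo1 was not called without luciferase siRNA replicate 2 (adjusted p = 0.299), nor Ndufa4 without replicate 1 (adjusted p = 0.263). Called in the same direction at both days were 972 higher genes (501 expected for independent calls) and 899 lower genes (391 expected), while 227 and 211 were called in opposite directions. These expectations also give every gene the same probability of a call whatever its read count.

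The luciferase siRNA libraries of day 6 were far shallower than those labelled Nudt21 siRNA, and the expression calls fell to 2244 without luciferase replicate 1 and to 2156 without replicate 2. Against untransfected day 6 cells, a control chosen after the data were seen, pluripotency genes rose in 9 of 13, epithelial in 8 of 12 and proliferation in 18 of 20, and mesenchymal genes fell in 21 of 29. Against the luciferase siRNA libraries of day 3, of similar depth but another day, pluripotency genes rose in 11 and epithelial genes in 10, and mesenchymal genes fell in 22. In contrast 20 of 20 proliferation genes fell (adjusted p = 1.29e-14, and adjusted p = 0.00601 with an estimated correlation). So did 18 of 18 interferon genes (adjusted p = 6.73e-14, and adjusted p = 0.00867 with an estimated correlation). With that control 54.7% of the genes reported higher at day 6 and 61.1% of those reported lower kept their sign, while 549 and 342 of them were called in the opposite direction.

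**Figure D4:**
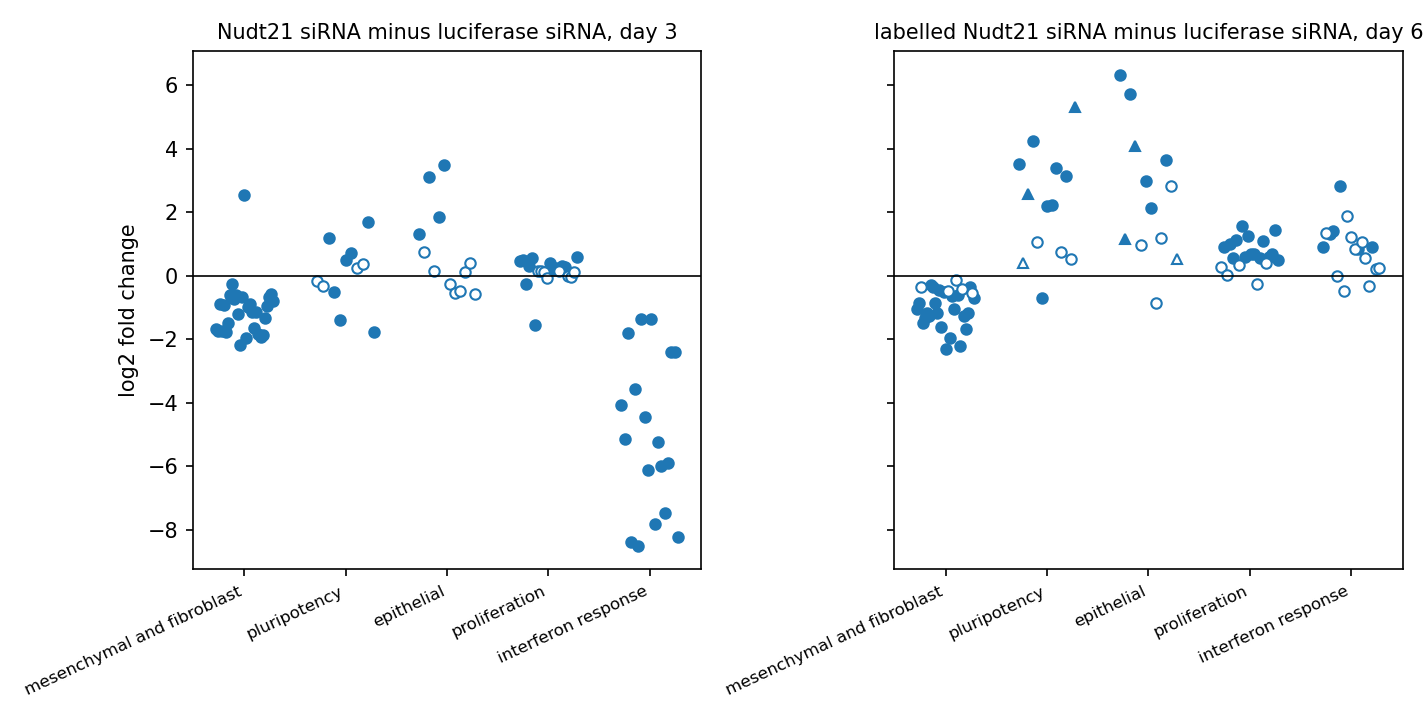
Log2 fold change (vertical axis) of each member of 5 gene lists, Nudt21 minus luciferase siRNA at day 3 (left) and libraries labelled Nudt21 siRNA minus luciferase siRNA at day 6 (right), filled symbols for called genes, open ones for genes not called, and triangles for lower bounds against 0 counts. At day 3 28 of 29 mesenchymal genes and 18 of 18 interferon genes fell, and at day 6 8 of 13 pluripotency genes rose.

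The difference between both siRNA effects was tested as an interaction, day 6 minus day 3, in which day 6 directions rest on the label. Only the day 6 effect set deeper against shallower libraries, so the interaction does not separate day from depth. Expression effects differed in 2973 genes and site effects in 1765, of which 1593 differed toward distal at day 6 in the fitted ratio, by a smaller shift to proximal or by a shift to distal. Of 1758 called pairs with a distal share in each group, 65 had a percent difference of the opposite sign. Among the lists interferon genes had the highest median difference, with 17 of 18 called (17 adjusted over the list alone) and a median of 6.26, or 6.18 without a gene that has no bound (adjusted p = 2.33e-41, and adjusted p = 0.00263 with an estimated correlation), Ifi44 by 9.80 (SE 0.45), Isg15 by 8.66 and Usp18 by 8.47. The size of this difference rests on the luciferase siRNA libraries of day 3, in which these genes were raised against untransfected cells. With untransfected cells as control the list's median was 0.12 at day 3 and 1.68 at day 6. Cldn6 (adjusted p = 8.97e-06) and Lsr (adjusted p = 0.00199) gave higher effects at day 6, where their control had 0 counts. Lum had a lower effect by -4.85 (SE 0.81), Gpc2 by -2.92, Acsbg1 by -2.71, Avil by -2.62 and Lars2 by -2.55. The shifts to proximal of day 3 in Hipk3 (-82.7 points), Fndc3a (-74), Atl2 (-55.8) and Fam33a (now Ska2, -65.7) stood against changes of -13.3, -1.32, 10.3 and 4.95 points at day 6. The differences were 69.4, 72.7, 66.1 and 70.6 points. The day 6 control of Atl2 held 5 proximal reads and 1 distal read, and that of Fndc3a had an SD of 24.4 points. Gls went from 67.7 points to distal at day 3 to 2.81 at day 6, a difference of -64.9. Prdm2 went from 19.9 to -12.3, a difference of -32.2. Sh3bgrl2, at -65.0 points, had 5 control reads at day 6. Nedd1, Gpc6 and Dync1i2 had control proximal sites at 0 at day 6 and a fitted difference that turned with another tool or control, while their percent differences were 24.2, 33.1 and 21.9 points. Without luciferase siRNA replicate 2 of day 6 expression effects differed in 1890 genes, and with thinned libraries site effects differed in 857.

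Luciferase siRNA libraries were also compared with those of untransfected cells. At day 3 interferon genes rose in 18 of 18 (18 adjusted over the list alone), with a median of 5.08, or 4.42 with 1 at its bound (adjusted p = 9.78e-72, and adjusted p = 0.00263 with an estimated correlation). The 5 largest rises were Isg15 (7.94, SE 0.16, 310 against 1.31 CPM), Oasl2 (7.87), Ifi44 (7.77), Rtp4 (7.49) and Usp18 (7.40), all interferon-induced. Mesenchymal genes also rose in 16 and fell in 2 of 29 (16 and 3 adjusted over the list alone), with a median of 0.29 (adjusted p = 1.83e-09, and adjusted p = 0.0306 with an estimated correlation), and p53 and senescence genes fell in 7 and rose in 1 of 13 (adjusted p = 0.00169, and adjusted p = 0.0464 with an estimated correlation). The p53 call ended after thinning (adjusted p = 0.0592). The largest falls were Tdh (-1.66, SE 0.16), Mgst2 (-1.66), Gna14 (-1.62), Notch3 (-1.61) and Bex1 (-1.59). With the preset correlation alone proliferation rose in 11 of 20 (13 adjusted over the list alone; adjusted p = 0.000198, and adjusted p = 0.0695 with an estimated correlation), and epithelial (3 of 12, adjusted p = 0.0252, and adjusted p = 0.179 with an estimated correlation), translation (12 of 15, or 14 adjusted over the list alone, adjusted p = 1.12e-05, and adjusted p = 0.22 with an estimated correlation) and oxidative phosphorylation genes (6 of 15, or 7 adjusted over the list alone, adjusted p = 0.00845, and adjusted p = 0.201 with an estimated correlation) fell. Expression differed in 2438 genes (1258 higher), 418 after thinning, 1393 without luciferase siRNA replicate 1 and 1312 without untransfected replicate 2. The epithelial call ended without luciferase siRNA replicate 1 (adjusted p = 0.139) or untransfected replicate 1 (adjusted p = 0.0681), and after thinning (adjusted p = 0.363).

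Site use differed in 22 genes between luciferase siRNA and untransfected cells at day 3, 12 to proximal and 10 to distal. Irf9, an interferon-signalling factor, gained its distal site (84.8 ± 2.11 against 50.6 ± 3.89%), as did Dst (94.8 against 87.4%), Ptgs2 (83.1 against 73.9%) and Bcap31 (93.9 against 90.0%). Zfp568 (64.6 against 78.5%), Gabpb1 (75.4 against 85.6%), Gls (17.9 against 29.5%), Setd7 (88.6 against 93.5%), Stox2 (62.0 against 74.2%) and Cggbp1 (54.7 against 67.2%) moved to proximal. The number was 9 without untransfected replicate 2, and Zfp568, Gabpb1, Setd7, Stox2, Cggbp1, Ptgs2 and Bcap31 were not among them (adjusted p = 0.465, 0.616, 0.167, 0.135, 0.465, 0.274 and 0.274). Each of these genes was also lost without luciferase siRNA replicate 1 or 2.

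At day 6 427 genes differed between luciferase siRNA and untransfected cells, 219 higher and 208 lower, at the lowest depth of the series. Usp18 was at least 14.8-fold higher and Apol9b higher by a ratio of 12.1 (interval 3.54 to 64.3), followed by Mgam (2.49, SE 0.72), Serpinb9b (2.34) and Gatm (2.24). Cadm1 was lower by a ratio of 20.3 (interval 3.44 to 820), Efs by 8.24 (2.66 to 41.3) and Nt5e by 7.67 (1.95 to 66.1), and Pltp changed by -2.06 and the growth factor gene Igf2 by -2.05 (SE 0.16). No list was called with an estimated correlation. With the preset one, interferon (2 of 18 higher, adjusted p = 0.000892, and adjusted p = 0.165 with an estimated correlation), proliferation (1 of 20, adjusted p = 0.00842, then 0.159), neural (2 of 9, adjusted p = 0.00135, then 0.112) and published target genes (1 of 15, adjusted p = 0.0337, then 0.179) were higher, and pluripotency (1 of 13 lower, adjusted p = 0.0119, then 0.112) and translation genes (0 of 15 called, adjusted p = 0.000818, then 0.347) lower, each second value being the adjusted p with an estimated correlation. Adjusted over the list alone, interferon and proliferation genes rose in 3 and 2 and pluripotency genes fell in 4. The neural mean was -0.06 against a median of 0.36. Without luciferase replicate 1 the translation list had an adjusted p of 0.367 and the published targets 0.0657, without luciferase replicate 2 the published targets had 0.0585, and without untransfected replicate 2 they had 0.155 and the neural list 0.0789. Site use differed in 5 genes, all to distal, Caprin1 (71.1 ± 7.13 against 47.2 ± 2.18%), Dst (75.8 against 55.9%), Ccdc72 (now Tma7, 53.1 against 34.8%) and Rpl13a (5.55 against 3.24%) meeting the rule, while 353 had an unadjusted p under 0.05 and limma voom called 0. Apol9b, Mgam, Gatm, Cadm1 and Nt5e were not called without luciferase replicate 1 (adjusted p = 0.244, 0.127, 0.085, 0.0815 and 0.264). Mgam, Gatm, Efs and Nt5e were not called without luciferase replicate 2 (adjusted p = 0.198, 0.151, 0.0683 and 0.177), and Mgam, Gatm and Nt5e without untransfected replicate 2 (0.0649, 0.141 and 0.18). Expression calls were 170 without luciferase replicate 1, 247 without luciferase replicate 2 and 231 without untransfected replicate 1, and site calls were 0 without luciferase replicate 1 or untransfected replicate 1 and 3 without either of the other libraries.

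**Figure D5:**
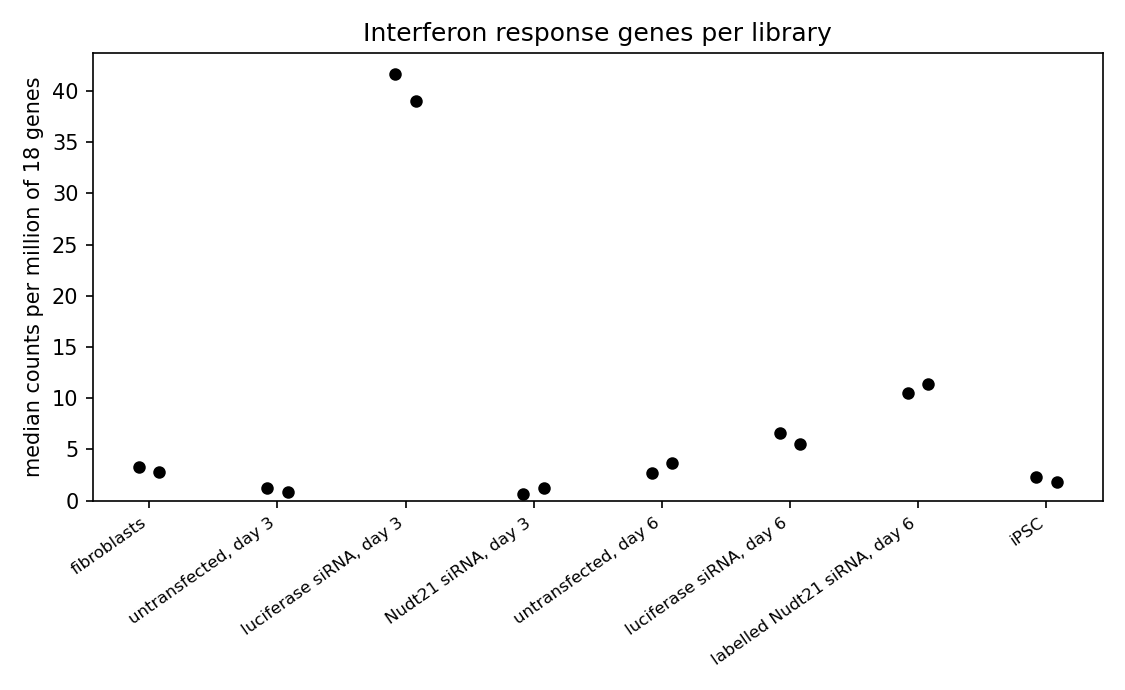
Median counts-per-million of 18 interferon response genes (vertical axis) in each library, 1 point per library. The luciferase siRNA libraries of day 3 lay at 41.7 and 39.0, against 0.688 and 1.29 with Nudt21 siRNA and 1.26 and 0.888 in untransfected cells of that day.

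Untransfected cells against MEFs follow reprogramming without siRNA. After 3 days of OKSM mesenchymal genes fell in 26 and rose in 3 of 29, with a median of -2.27 (adjusted p = 2.66e-15, and adjusted p = 0.0147 with an estimated correlation), glycolysis genes fell in 13 and rose in 1 of 14 (adjusted p = 8.22e-07, and adjusted p = 0.0336 with an estimated correlation), and proliferation genes rose in 20 of 20 with a median of 2.1 (adjusted p = 1.73e-14, and adjusted p = 0.0147 with an estimated correlation). The preset correlation alone called 4 other lists as higher: cleavage and polyadenylation factors (15 of 20, adjusted p = 0.00363, and adjusted p = 0.0988 with an estimated correlation), trithorax and COMPASS (10 of 14, adjusted p = 0.00572, and adjusted p = 0.22 with an estimated correlation), Polycomb (15 of 22, adjusted p = 0.0288, and adjusted p = 0.112 with an estimated correlation) and BAF and chromatin assembly (11 of 15, adjusted p = 0.0111, and adjusted p = 0.249 with an estimated correlation). Counts adjusted over the list alone were the same for these 7 lists. Nefl, a neurofilament gene, rose at least 125-fold to 55.2 CPM, the adhesion gene Ceacam1 at least 107-fold, Pthlh 42.8-fold and St3gal6 41.4-fold, and Tmem35 (now Tmem35a) by 7.87 (SE 0.26). Gzme fell by a ratio of 553 (interval 188 to 2690), Tnfsf15 by 236 (41.1 to 9448), Nxph4 by 163 (54.6 to 797) and the collagen gene Col8a2 by 162 (43.6 to 1352), and Slc1a6 changed by -6.95 (SE 0.25). In all 4272 genes were higher and 3907 lower, in a comparison that set deeper against shallower libraries.

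Site use at day 3 of OKSM went to proximal in 735 and to distal in 970 genes. Esyt1 (5.53 against 46.9% distal), Brip1 (55.3 against 95.0%), Loxl2 (71.9 against 97.3%), Gm17296 (now Tarbp1, 49.8 against 92.2%), the fibroblast transcription factor gene Twist2 (30.6 against 84.8%) and 9830001H06Rik (now Soga1, 65.7 against 95.9%) led the shifts to proximal in the fitted ratio, and Ccdc43 (89.7 against 31.1%), H2afj (now H2aj, 12.6 against 1.12%), Ubtd2 (88.8 against 39.6%) and Jmy (66.7 against 15.1%) those to distal. Leaving out MEF replicate 1 or 2 gave 1122 or 1117 calls, and 418 were left with thinned libraries.

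After 6 days mesenchymal genes were lower in 23 and higher in 3 of 29 (adjusted p = 1.91e-18, and adjusted p = 0.0111 with an estimated correlation) and glycolysis genes lower in 11 of 14 (adjusted p = 1.84e-10, and adjusted p = 0.0133 with an estimated correlation). Proliferation genes were higher in 9 and lower in 1 of 20 (11 and 1 adjusted over the list alone; adjusted p = 0.0164, and adjusted p = 0.179 with an estimated correlation). Ceacam1 rose at least 132-fold, Fmo1 71.9-fold, Nefl 58.3-fold, Ecel1 42.4-fold and Sp9 34.8-fold. Nxph4 was at least 23.0-fold lower, Ifi27l2b 12.2-fold, Olr1 11.3-fold and Bmpr1b 10.9-fold, and the lactate transporter gene Slc16a3 was lower by a ratio of 161 (interval 44.4 to 1331). Expression differed in 4861 genes (2347 higher). Site use went to proximal in 16 and to distal in 154 genes. Dst (55.9 against 97.0%), Gfod2 (15.7 against 69.7%), Mdga1 (0 of 14 reads against 42.1%, up to 21.4% allowed), Loxl2 (88.0 against 97.3%), Map3k10 (20.5 against 47.3%) and Twist2 (63.1 against 84.8%) moved to proximal, and Parn, a deadenylase gene (95.6 against 53%), Ptprd (92.9 against 58.2%), Ccdc50 (96.9 against 77.9%) and Map2k1 (100 against 91.8%, with a proximal share of up to 3.45% allowed) to distal. Site calls were 79 and 45 without untransfected replicate 1 or 2 and 97 and 83 without MEF replicate 1 or 2. Mdga1, Loxl2, Map3k10, Twist2, Ptprd and Map2k1 were not called without untransfected replicate 2 (adjusted p = 0.412, 0.158, 0.142, 0.405, 0.644 and 0.322). Mdga1, Map3k10, Ptprd and Map2k1 were also lost without untransfected replicate 1 (adjusted p = 0.182, 0.0911, 0.0592 and 0.193).

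In iPSCs, the end state, pluripotency genes rose against MEFs in 13 of 13 (median 7.31, or 6.56 with 1 at its bound, adjusted p = 1.14e-09, and adjusted p = 0.0315 with an estimated correlation), mesenchymal genes fell in 28 of 29 (median -4.42, adjusted p = 5.49e-23, and adjusted p = 0.0132 with an estimated correlation) and proliferation genes rose in 20 of 20 (adjusted p = 1.73e-14, and adjusted p = 0.0306 with an estimated correlation). Adjusted over the list alone these counts were the same. The preset correlation alone called 8 others as higher, each followed here by the adjusted p with an estimated correlation: epithelial (10 of 12, adjusted p = 0.000466, then 0.124), cleavage and polyadenylation factors (19 of 20, 0.000734, then 0.0695), trithorax and COMPASS (11 of 14, 0.00175, then 0.179), Polycomb (15 higher and 6 lower of 22, 0.0197, then 0.0988), BAF and chromatin assembly (13 and 2 of 15, 0.00323, then 0.206), translation (10 and 2 of 15, 0.0265, then 0.537), oxidative phosphorylation (13 and 1 of 15, 0.00842, then 0.22) and glycolysis (14 of 14, 1.94e-05, then 0.0988). The tight junction gene Cldn4 reached 129 CPM, at least 292-fold higher, Lrrc34 at least 239-fold, the transcription factor gene Otx2 137-fold, Nefl 137-fold and Slc39a4 137-fold. Megf10 was at least 62.8-fold lower, Kcnmb1 60.1-fold and Asb5 48.8-fold, and Fibin changed by -8.76 (SE 0.30) and Mylk, which drives smooth muscle contraction, by -8.52. Expression differed in 9601 genes, 5161 higher and 4440 lower, again with deeper libraries set against the MEFs.

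Site use in iPSCs went to proximal in 892 and to distal in 481 genes (65.0% proximal). Intronic sites gained in Dido1 (distal share 18 ± 1.98 against 87.2 ± 2.07%), Prdm2 (30.9 against 93.2%) and Rps6kc1 (48.9 against 97.1%), and proximal last exon sites in Loxl2 (54.0 against 97.3%), Klf9 (89.4 against 99.6%) and the DNA methyltransferase gene Dnmt3a (21.0 against 86.8%). Distal sites gained in Iqce (100 against 31.4%, with up to 5.36% allowed at the proximal site), Hsd17b14 (79.6% against 0 of 9 reads), Phf14 (37.7% against 0 of 25 reads) and Hectd2 (94.7 against 33.2%). Calls were 889 without MEF replicate 2 and 286 with thinned libraries.

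Whether the siRNA moved genes in the direction of reprogramming was described by correlation across genes, which are not independent replicates. Log2 fold changes at day 3 correlated with those of iPSCs against MEFs at r = 0.328 (Spearman 0.356, 12449 genes), and at day 6, in the libraries labelled Nudt21 siRNA, at r = 0.451 (Spearman 0.466). These comparisons share no libraries, but the siRNA comparison of day 6 and that of iPSCs with MEFs both set deeper against shallower libraries. Changes in site use correlated at r = 0.110 (Spearman 0.114, 5706 genes) at day 3 and at 0.141 (Spearman 0.188) at day 6. Untransfected day 6 libraries were shallow like those of the MEFs. With them in place of iPSCs expression correlations were 0.164 and 0.0923, and those of site use turned to -0.168 and -0.140. With untransfected day 3 cells against MEFs expression correlated at 0.269 and 0.213 (Spearman 0.264 and 0.415). Site use correlated at -0.0745 for day 3 and 0.152 for day 6 (Spearman -0.0946 and 0.227). For both days the sign of site use differed with the reference comparison. At day 6 it was positive with iPSCs and untransfected day 3 cells, which set deeper libraries against the MEFs. It was negative with untransfected day 6 cells, which did not, so stage and depth cannot be told apart there. The siRNA effects of day 3 and day 6 correlated at 0.308 in expression and 0.362 in site use (Spearman 0.352 and 0.411). In all 14 such relations were computed, with no p given.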

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

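The tests on Nudt21 mRNA at day 6 and on interferon genes at day 3 were chosen after their results were seen, and those on expression at day 6 were written before.

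The effect of Nudt21 against luciferase siRNA differed between days 6 and 3, by an interaction test with edgeR, in the expression of 2973 genes and in the site use of 1765. Day 6 directions rest on the label of the libraries, and only the day 6 effect set deeper against shallower libraries. Nudt21 itself differed by 1.72 log2 units (SE 0.25, adjusted p = 5.88e-09). Among the lists the median difference was 6.26 for interferon genes, or 6.18 without a gene that has no bound (adjusted p = 2.33e-41, and adjusted p = 0.00263 with an estimated correlation). Its size rests on the raised level in the luciferase siRNA libraries of day 3. Against untransfected cells the interferon median was 0.12 at day 3 and 1.68 at day 6. The other list differences did not pass with an estimated correlation: 2.29 for pluripotency, or 1.57 with genes at 0 counts at their bounds or left out (adjusted p = 0.00282, then 0.0736), 2.42 for epithelial, or 1.88 in that way (0.0152, then 0.165), 0.24 for mesenchymal (0.0222, then 0.263) and 0.44 for proliferation genes (0.000259, then 0.0736). Translation stood at -0.63 (8.23e-11, then 0.112), oxidative phosphorylation at -0.32 (0.000219, then 0.0994) and glycolysis at -0.50, or -0.54 in that way (0.00135, then 0.112), with a glycolysis mean of 0.04. Without luciferase siRNA replicate 1 of day 3 the mesenchymal difference had an adjusted p of 0.0700, without luciferase siRNA replicate 2 of day 6 it had 0.0585, and the epithelial difference without luciferase siRNA replicate 2 of day 3 had 0.0685.

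Single genes whose expression effect differed were Prrg4 (-2.55, adjusted p = 0.00122), Ifi44 (9.80), Usp18 (8.47), Isg15 (8.66), Oasl2 (7.13), Mapk11 (-2.09, with 3.99 and 17.9 CPM in its 2 control libraries of day 6) and Tmc3 (-1.51). Ifit1 (adjusted p = 6.87e-28), Mmrn2 (adjusted p = 0.00586) and Cldn6 (adjusted p = 8.97e-06) had 0 to 3 counts in a group, so no fold is given. For site use, the change in distal share was higher at day 6 than at day 3 by 43.3 points in Jmjd1c, 46.1 in Zswim6, 47.8 in Prkx, 41.0 in Rapgef2, 47.7 in 2610528E23Rik, 55.0 in Ccdc43 and 37.1 in Cdk8. It was lower in Papd5 (-40.1), Gls (-64.9) and Araf (-36.5). Fgfr1op, Dync1i2, Abca1, Fndc3b, Xrn1 and Enox2 had 0 proximal reads in their day 6 control, and the tested log2 ratio differed in the opposite direction to the share. Their fitted log2 differences, which have no exact value at 0 reads, were -4.24, -5.19, -3.30, -1.26, -2.28 and -3.96, and their shares differed by 30.2, 21.9, 31.1, 42.2, 51.1 and 25.4 points, so no direction is given. For Dync1i2 the log2 difference was 0.50 with untransfected controls.

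Uty, a gene of the Y chromosome, had 5 counts in the SSEA-positive library of day 6 and 4 in that of day 9, and 0 in the 16 libraries of the replicated groups. Xist, expressed from an inactive X chromosome, stood at 0 and 0.0887 CPM in these libraries, and at 86.9 to 311 CPM in the replicated libraries of fibroblasts and induced cells. The replicated iPSC libraries were also low in Xist, at 5.01 and 7.10 CPM, with 0 counts of Uty. The labels do not give the sex of the embryos.

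Nudt21 mRNA was not lower at day 6 in the libraries labelled Nudt21 siRNA. A wrong label is argued against by site use, since the changes of days 6 and 3 correlated across 5706 genes at a Spearman rho of 0.411, against 0.0768 for untransfected day 3 minus day 6. Recovery of the mRNA may contribute: in libraries with that label Nudt21 was higher at day 6 than at day 3 by 0.39 log2 units (SE 0.12, adjusted p = 0.00374). The siRNA effect on Nudt21 differed between the days by more, 1.72 log2 units (SE 0.25), so this rise alone does not account for it. A lower reading in shallow libraries stays open, because against luciferase siRNA libraries of day 3 the day 6 libraries were at -1.14 (SE 0.11, adjusted p = 8.42e-19), a comparison that also crosses days. These explanations cannot be told apart here, as every control of day 6 is shallow. The single SSEA-positive libraries, with 6019370 counts at day 6 and 11881075 at day 9, stood at 32.5 and 37.7 CPM for Nudt21. They hold sorted cells without replicates, so they cannot decide whether shallow libraries read low.

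Expression at day 6 set deep against shallow libraries. After thinning, log2 fold changes of 3329 called genes followed the full ones with a slope of 0.866. The changes therefore do not need the extra reads of the deeper libraries. Thinning keeps the expected ratio between the same libraries, so it cannot decide on a cause that goes with shallow libraries. Another difference between the deep and shallow sets cannot be told apart from the siRNA, with a Pearson correlation of 0.165 across genes with untransfected day 3 minus day 6 (Spearman 0.374). A siRNA effect shared with day 3 is a candidate explanation for part of the change, at a Spearman rho of 0.352 across genes.

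Interferon genes were lower with Nudt21 than with luciferase siRNA at day 3. Against untransfected cells the list's median with Nudt21 siRNA was 0.12 log2 units at day 3. This cannot decide on a response to any siRNA, because such a response countered by loss of Nudt21 would read the same. At day 6 the list rose in 13 and fell in 0 of 18 in the libraries labelled Nudt21 siRNA against untransfected cells. Its median was 1.68 (camera adjusted p = 3.98e-05, and adjusted p = 0.0862 with an estimated correlation), with deeper set against shallower libraries. Whether loss of Nudt21 lowers these genes below the untransfected level at day 3 stays open. Of 18 genes 1 fell at day 3, but 13 of 18 stood under 5 CPM in untransfected cells, where a fall could hardly be called. What in the luciferase siRNA libraries raised the genes was not tested.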

How the results depend on the processing

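Thinning, untransfected or day 3 luciferase controls, leaving out luciferase-changed genes and untransfected day 6 cells in place of iPSCs were chosen after seeing the data. Of 105 values for expression counts 86 stayed within 1.5 times the reported count, as did 75 of 112 for site counts. For the share of shifts to proximal 61 of 73 values, for list calls 21 of 22 and for agreement with reprogramming 43 of 75 stayed close. Except where a construction is named, the cause was not tested.

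With a fold of at least 1.5, which removes genes by construction, expression calls were 3451 for Nudt21 against luciferase siRNA at day 3 and 901 and 279 for luciferase siRNA against untransfected cells at days 3 and 6. A change of 15 points left 370 site calls for the siRNA at day 6, 843 and 89 for untransfected cells of days 3 and 6 against MEFs, 767 for iPSCs, and 7 and 3 for luciferase siRNA at days 3 and 6. A Simes p over all sites gave 56 for untransfected day 6 cells and 9 and 1 for luciferase siRNA at days 3 and 6. Groups fitted alone gave 8 and 3 site calls for luciferase siRNA at days 3 and 6. With voom untransfected day 6 cells had 95 and luciferase siRNA at day 6 had 0, and the proximal share was 86.2% at day 6 and 16.8% for untransfected day 6 cells. With an estimated correlation 18 list tests passed.

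After thinning, which lowers depth, expression calls were 2247 for the siRNA at day 3, 4824 and 2887 for untransfected cells of days 3 and 6, 6133 for iPSCs, 418 for luciferase siRNA at day 3 and 1391 for the interaction. Site calls were 1468, 418, 45, 286 and 2 in the same order and 857 for the interaction, with 2 for luciferase siRNA at day 6. The proximal share was 95.7% at day 3 and 17.8% for untransfected day 6 cells.

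With untransfected cells as control, the siRNA at day 6 gave 5375 expression and 1418 site calls, 87.1% of them proximal. With the luciferase siRNA libraries of day 3 as control it gave 6819 and 1721, 82.4% proximal. In expression 54.7% of the 1833 genes reported higher and 61.1% of the 1668 reported lower kept their sign with that control. Of these genes 549 and 342 were called in the opposite direction. A site minimum of 30 counts gave 93.2% proximal at day 3, and last exon sites alone 94.5% at day 3 and 94.4% at day 6. Replicate number as a block, which the pairing check did not favour (28 correlations with a median of -0.0079), gave 6259 expression and 3773 site calls at day 3, 3519 and 612 at day 6, and 3 site calls for luciferase siRNA at day 6. With it the p53 list of day 6 was no longer called (adjusted p = 0.0520).

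Agreement of the siRNA effect with iPSCs against MEFs was reported as 0.328 and 0.451 for expression at days 3 and 6 and 0.110 and 0.141 for site use. For expression it was 0.407 at day 6 with the Wald test, 0.426 and 0.547 for genes of at least 10 CPM, 0.430 and 0.525 with groups alone, 0.255 and 0.345 without a filter, 0.289 at day 3 without luciferase-changed genes, 0.508 at day 6 after thinning, 0.226 and 0.393 with untransfected controls, and 0.346 at day 6 with day 3 luciferase siRNA libraries. For site use it was 0.173 at day 6 for genes of at least 10 CPM, 0.0765 and 0.196 with voom, 0.182 at day 6 with a site minimum of 30 counts, 0.0395 and 0.172 after thinning, 0.0891 and 0.186 with untransfected controls and 0.0564 at day 6 with day 3 luciferase siRNA libraries. With untransfected day 6 cells in place of iPSCs it was 0.164 and 0.0923 for expression, and for site use it reversed to -0.168 and -0.140. The Simes setting gives no shift per gene and was not run for agreement, and the 2 alternatives of the SSEA comparison were not run.

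Leaving out each replicate gave 2156 to 3225 expression and 275 to 529 site calls for the siRNA at day 6. Site calls were 1117 to 1571 and 45 to 97 for untransfected cells of days 3 and 6 and 889 to 1093 for iPSCs. For luciferase siRNA expression calls were 1312 to 2303 at day 3 and 170 to 311 at day 6, and site calls 9 to 31 and 0 to 3. The interaction had 1890 to 2965. The proximal share was 92.4 to 93.2% at day 3 and 65.0 to 68.5% in iPSCs. Agreement was 0.262 to 0.336 and 0.378 to 0.456 for expression and 0.0818 to 0.119 and 0.0975 to 0.154 for site use. A group left with 1 library was assumed to vary like the others.

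Of 2008 values for named expression results, 1936 kept direction and call, 47 were weaker, 3 stronger and 22 reversed. For named site results 760 of 857 were the same, 91 weaker and 6 reversed. At day 3 against untransfected cells Isg15 was 0.12, Oasl2 0.40, Serpine1 0.47, Trp53inp1 -0.11, Sfn 1.46 and Fhl1 0.0726, and Des was 3.10 after thinning. At day 6 against day 3 luciferase siRNA libraries Fmo1 was 0.11, Cpsf3 -0.25, Dpy30 -0.53, Leo1 -0.30, Hdac1 -0.45, Cdc20 -0.69, Top2a -0.93, Ddx58 -0.35, Bst2 -1.62, Tek 0.19, Eef2 0.15, Rps8 0.16, Cox4i1 0.55, Ndufa4 -0.14 and Timp2 0.0167, and the site change of Ccdc43 was -0.51. In the interaction the site difference of Dync1i2 was 0.50 with untransfected controls, that of Nedd1 0.11 with voom and 1.91 with untransfected controls, and that of Gpc6 0.58 and 3.33.

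Depth limits what can be called, although thinning left 2604 expression and 472 site calls for the siRNA at day 6, within 1.5 times of those reported. The calls of mesenchymal and interferon genes at day 3 and of pluripotency, epithelial, mesenchymal and proliferation genes at day 6 held in the 22 alternatives run for the lists of every comparison, which leave out the other controls. Of these alternatives 16 left out 1 library each, and for either day only 4 of them removed a library of the groups compared. Against untransfected cells the interferon call of day 3 was lost (adjusted p = 0.905), as were those of cleavage factors (0.0874), p53 (0.0882) and glycolysis genes (0.117) at day 6. Against day 3 luciferase siRNA libraries the day 6 calls reversed for proliferation (20 of 20 fell, adjusted p = 1.29e-14) and interferon genes (18 of 18 fell, 6.73e-14), and were lost for cleavage factors (0.269), trithorax (0.905), Polycomb (0.328), translation (0.75) and glycolysis genes (0.327). After thinning, adjusted p was 0.0561 for interferon genes at day 6, 0.0524 and 0.101 for cleavage factors and Polycomb in untransfected day 3 cells, 0.363 and 0.0592 for epithelial and p53 genes with luciferase siRNA at day 3, and 0.0593 for published targets with luciferase siRNA at day 6. Epithelial and pluripotency differences in the interaction had 0.125 and 0.259, and the keratinocyte list of day 6 could not be tested.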

Other observations

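The test on site shift and expression was written before its result was seen.

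The single SSEA-positive libraries of days 6 and 9 enter no comparison and have no replicates. Their median CPM was 6.46 and 8.51 for pluripotency, 0.960 and 2.08 for epithelial, 49.8 and 29.8 for mesenchymal and 0.698 and 0.532 for interferon genes. Nudt21 stood at 32.5 and 37.7 CPM.

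A shift to the proximal site may go with a higher transcript level. Across 5706 genes at day 3 the change in log2(distal/proximal) correlated with the log2 fold change at a Spearman rho of -0.14, and genes are not independent replicates. Genes shifted to distal were also higher in 45.3% of cases, so direction alone does not account for it.

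At day 3 pairs of an intronic and a last exon site had a median change in log2(distal/proximal) of -0.67, and pairs within the last exon -1.40. At day 6, in the libraries labelled Nudt21 siRNA, 18 of 35 called shifts in the former and 536 of 569 in the latter were proximal. These are values without a test of the difference.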
